A study of Mus musculus with 6 samples.

How the data were processed

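RNA sequencing was done on 6 libraries of RAW264.7, a mouse macrophage-like cell line. Cells carried either a lentiviral vector with Fbxw11 and a GFP marker (3 libraries) or the control vector (3 libraries), and were sorted before RNA extraction, per the labels. The control libraries are named for GFP, but what their vector holds is not described further, so GFP is not to be read as a difference between the groups. Total RNA was purified on columns and libraries followed standard Illumina protocols, per the labels' protocols. Whether the kit selected polyadenylated RNA, marked strand or paired reads is not given in the sources used here. Nothing in the labels says that the 3 libraries of a group came from separate transductions or cultures, so p-values measure only the spread between these libraries, which may be technical.

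The deposited table holds FPKM, fragments scaled to gene length and library size by the authors, for 56748 Ensembl mouse genes, with 1 column per library and with each gene's name, biotype, length and coordinates. The genome build is mm10, per the submitters' processing notes. The aligner, the counting tool, the annotation release and any filter are not given in the sources used here. The table's coordinates were compared with a GENCODE annotation of that build. Of 52036 nuclear gene identifiers in both, 1435 (2.76%) had the same start and end, while 96.8% had the same span. The coordinates therefore do not follow the build named in the labels, and those printed are the file's own, with their build not stated.

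Multiplied by the gene length in the file, every FPKM value above 0 was a whole multiple of a single step per library (100% of values within 0.02 reads of a whole number), so reads per gene could be recovered. Recovered reads summed to between 16191971 and 18951653 per library. The library size that the authors divided by lay between 0.987 and 1.02 times that sum, so a scaling step beyond the plain sum had been applied. It differed by group, at 1.014 to 1.018 times the sum in control and 0.987 to 0.993 in Fbxw11 libraries. Against plain sums, this raised FPKM in the Fbxw11 libraries relative to the controls. FPKM is a normalized value and the main test did not use the recovered reads. They give the depth behind each value and an alternative test. Reads are not independent molecules without molecular identifiers, and intervals or floors built on them cover counting error only.

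Values were analysed as log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the 6 libraries were tested, 10898 in all, with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided, no covariate). Every adjusted p is limma's with Benjamini-Hochberg adjustment, and the threshold was 0.05. "Rose" and "fell" describe genes past it, higher or lower in the Fbxw11 libraries. A log2 fold change on the log2(FPKM + 1) scale understates the change of genes with low FPKM, so the ratio of mean FPKM or both means are given beside it for many such genes. Errors are SD over n = 3 libraries for FPKM and standard errors (SE) for log2 fold changes.

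33 gene lists were fixed before the data were examined: markers of macrophage activation states, targets of signalling pathways, metabolic and cell cycle groups, and markers of other cell types. The 27 lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Beside it, camera was run with a correlation estimated from the data, and limma's fry, which asks whether a list's genes move on balance in the same direction and does not compare them with other genes. For each list the members past the threshold were counted over all genes tested and adjusted over the list alone.

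The genes named in the text follow a rule also fixed before the data were examined. It takes Fbxw11 and its paralog Btrc. It takes the 8 rises and 8 falls with the largest log2 fold change and the 4 rises and 4 falls with the highest FPKM among protein-coding genes past the threshold whose groups do not overlap. From each list it takes up to 4 members past the threshold with the smallest p, filled up to 2 with the most abundant members where fewer passed. The canonical polarization genes Nos2, Tnf, Il1b, Il6, Arg1, Mrc1, Cd86, Cd80, Il10 and Chil3 are given whatever their result. Some list members were left out for length, a few that the rule names are not reported here, and genes named outside the rule are said to be so.

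The whole procedure was tested on simulated data with the real means and depths, 10905 genes of them tested and 200 changed. Of 50 genes changed at each size it called 52% at 1.25-fold, 82% at 1.5-fold, 96% at 2-fold and 92% at 3-fold, with 7 false calls, and 1 call when no gene was changed. The simulation drew each gene independently with a single dispersion of 0.00153 for all genes. It held no difference that many genes of a library share. The real libraries may vary less evenly, so these rates may be too favourable for them. Alternatives set before the data were examined were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, TPM scaling, median-of-ratios scaling, quantile normalization, array weights, eBayes without trend, a block on the replicate number, protein-coding genes only, a minimum log2 fold change of 1, an adjusted p below 0.01, and each library left out in turn. Chosen after the data were seen were limma's voom on recovered reads, FPKM recomputed over plain read sums, and both libraries numbered 3 left out together. Counts of calls that a gene lost leave out the minimum log2 fold change and the adjusted p below 0.01. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for read recovery, library measures and figures.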

Results

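The transcriptome of RAW264.7 macrophages carrying an Fbxw11 vector was compared with that of cells carrying the control vector, 3 libraries of each. Fbxw11 encodes an F-box protein (β-TrCP2), a substrate receptor of the SCF ubiquitin ligase, and the series title places the comparison in the question of macrophage polarization. Recovered reads numbered 16191971, 18951653 and 16652376 in control libraries 1 to 3 and 16399644, 18019053 and 17270043 in Fbxw11 libraries 1 to 3. Between 10886 and 10949 genes reached 1 FPKM in each library. Every pair of libraries within a group differed by more than sampling noise (chi-square per degree of freedom 2.42 to 5.86), so none was treated as a copy of another. This does not tell whether the libraries came from separate cultures. The leading principal component held 33.8% of the variance and separated the groups. The next held 23.7% and set control library 3 and Fbxw11 library 3 apart from the other 4 libraries.

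Fbxw11 itself was measured as a check of the labels. Its transcript rose from 36.1 ± 0.409 FPKM in the control libraries to 271 ± 2.74 FPKM in the Fbxw11 libraries, a 7.51-fold difference (log2 fold change 2.88, SE 0.028, adjusted p = 8.54e-08). Between 2544 and 3040 reads per control library and between 19279 and 21008 per Fbxw11 library lay behind these values. Fbxw11 is placed on chromosome 11 at 32592724 to 32696816 in the file's coordinates, whose build is not stated. Reads from the vector and from the endogenous gene cannot be told apart in this value. Btrc, which encodes the paralog β-TrCP1, stood at 0.970 ± 0.0662 FPKM in control and 0.939 ± 0.0430 FPKM in Fbxw11 libraries, under the filter, and was not tested.

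**Figure D1:**
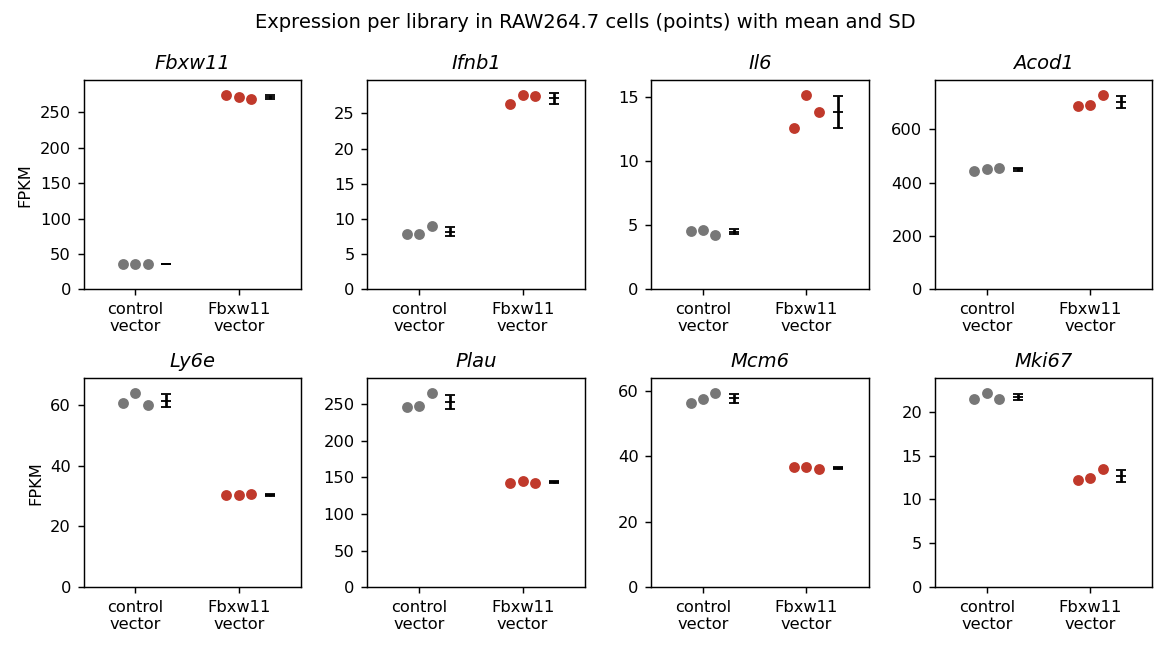
FPKM of 8 genes in each library (points, 3 per group), with the mean and SD of each group as a bar to the right of the points and the FPKM axis starting at 0. In each panel the 3 Fbxw11 libraries lie apart from the 3 control libraries, as for Fbxw11 at 36.1 against 271 FPKM and for Mki67 at 21.6 against 12.7 FPKM.

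Outside Fbxw11, the largest rises among protein-coding genes with groups that did not overlap included type I interferon genes and the cytokine gene Il6. Ifna5 rose from 1.55 ± 0.268 to 8.66 ± 0.712 FPKM (5.59-fold), Ifna2 from 1.40 ± 0.231 to 5.78 ± 0.428 FPKM (4.13-fold) and Ifna4 from 3.18 ± 0.215 to 11.4 ± 1.22 FPKM (3.57-fold). Ifnb1, the interferon-beta gene, rose from 8.22 ± 0.643 to 27.1 ± 0.735 FPKM (3.30-fold, log2 fold change 1.61, SE 0.056, adjusted p = 0.000146). Il6 rose from 4.51 ± 0.208 to 13.9 ± 1.26 FPKM (3.08-fold). Csf2, which encodes GM-CSF, rose from 5.89 ± 1.54 to 14.3 ± 1.94 FPKM (2.42-fold, adjusted p = 0.0122). Urah, the gene of 5-hydroxyisourate hydrolase in urate breakdown, rose from 6.93 ± 0.756 to 17.7 ± 1.55 FPKM (2.55-fold). The Ifna genes are near-identical copies of each other, and how the counting treated reads shared between them is not given in the sources used here. Their separate values are therefore uncertain.

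The largest falls, chosen in the same way, were smaller. Apol9a fell from 12.002 ± 0.781 to 5.44 ± 0.331 FPKM (2.21-fold) and its near-identical neighbour Apol9b from 33.4 ± 2.16 to 18.8 ± 2.17 FPKM (1.78-fold), so their separate values are uncertain too. Ly6e, a GPI-anchored surface protein gene induced by interferon, fell from 61.3 ± 2.10 to 30.4 ± 0.259 FPKM (2.02-fold, log2 fold change -0.99, SE 0.035, adjusted p = 0.000146). Plau, the gene of urokinase-type plasminogen activator, fell from 253 ± 10.0 to 143 ± 1.38 FPKM (log2 fold change -0.82). Tlr3, the receptor for double-stranded RNA, fell from 5.66 ± 0.373 to 2.87 ± 0.152 FPKM and Ifi27l2a from 42.4 ± 2.99 to 24.6 ± 3.34 FPKM. Lrr1, a substrate receptor of another ubiquitin ligase, fell from 5.63 ± 0.761 to 2.46 ± 0.504 FPKM. The meiotic recombination gene Mnd1 fell from 6.23 ± 1.32 to 3.05 ± 0.648 FPKM (adjusted p = 0.0258), a call lost under 5 alternatives.

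Of the 4 rises and 4 falls with the highest FPKM, Plau, given above, changed most. Sqstm1, the autophagy receptor p62, rose from 2038 ± 60.4 to 2506 ± 94.2 FPKM (log2 fold change 0.30, a call lost under 3 alternatives), Ptgs2, cyclooxygenase-2, from 1420 ± 18.7 to 1844 ± 77.9 FPKM (0.38) and the chaperone Hspa5 from 915 ± 5.77 to 1152 ± 24.5 FPKM (0.33). Lysozyme, Lyz2, rose from 2346 ± 70.9 to 2628 ± 39.2 FPKM (adjusted p = 0.0478), a call lost under 15 of 20 alternatives. Gpnmb, a lysosomal membrane glycoprotein, fell from 609 ± 7.10 to 507 ± 10.0 FPKM (log2 fold change -0.26) and carbonic anhydrase 2, Car2, from 531 ± 9.98 to 416 ± 12.1 FPKM (-0.35). Cystatin C, Cst3, fell from 223 ± 2.33 to 195 ± 8.07 FPKM (-0.19), a call lost under 7 alternatives. The 10 most abundant genes took 7.84% ± 0.0474 of reads in control and 8.44% ± 0.216 in Fbxw11 libraries.

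Over all genes, 1007 of 10898 changed (9.24%), of which 501 rose and 506 fell, and 958 of them were protein-coding. The median absolute log2 fold change of the changed genes was 0.31, and 16 reached an absolute value of 1, of which 14 rose and 2 fell. Groups did not overlap for 31.1% of tested genes, where chance gives 10%. Scaling moved the balance of directions: 348 rose and 712 fell on the TPM scale (32.8% rises against 49.8%), and 381 rose and 691 fell over plain read sums (35.5%). With a library left out, 447 genes passed without control library 1, 410 without control library 2, 568 without Fbxw11 library 1 and 532 without Fbxw11 library 2. More passed without control library 3 (737) or Fbxw11 library 3 (801).

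**Figure D2:**
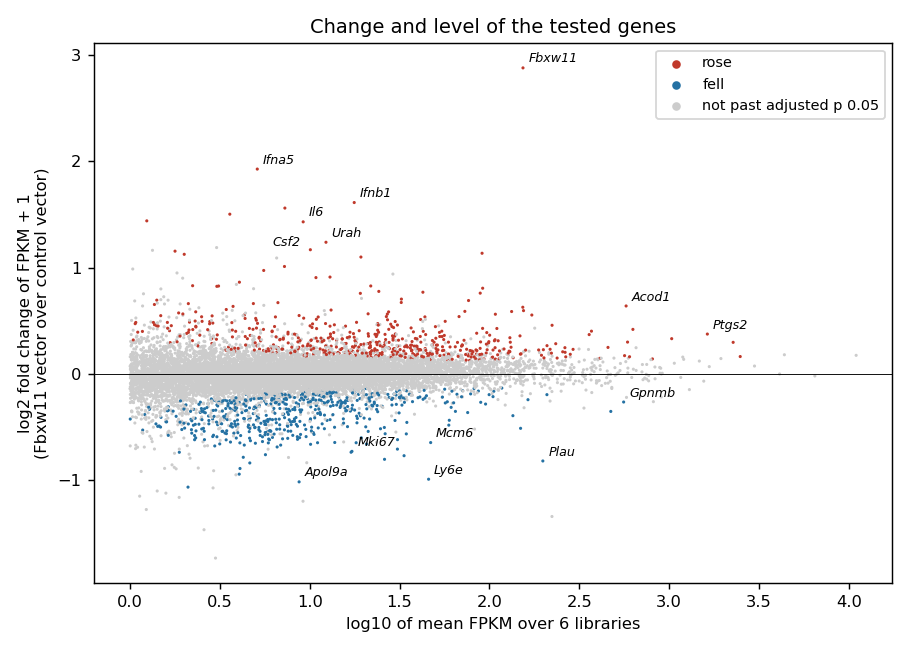
Log2 fold change of FPKM + 1 (Fbxw11 vector over control vector) against log10 of the mean FPKM over the 6 libraries, with each of 10898 tested genes as a point. The 501 rises are in red, the 506 falls in blue and the others in grey, and Fbxw11 stands highest at 2.88.

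Of the classical (M1) activation markers, 7 of 18 tested members rose and 0 fell, and adjusted over the list alone 12 rose and 1 fell. Ptgs2, Tnf, Acod1 and Nos2 were already abundant in the control libraries, at 1420, 467, 450 and 158 FPKM. Rises are therefore changes from such levels, and the sample titles do not say whether the cells were stimulated. Besides Il6 and Ptgs2, Acod1, which makes itaconate, rose from 450 ± 4.75 to 702 ± 21.5 FPKM (log2 fold change 0.64, SE 0.035, adjusted p = 0.000486). The CXCR3 ligand gene Cxcl10 rose from 31.3 ± 1.97 to 54.0 ± 3.86 FPKM (0.77) and the cytokine signalling inhibitor Socs3 from 20.5 ± 0.743 to 26.8 ± 0.664 FPKM (0.37). Other canonical markers did not pass over all genes tested, though Tnf and Cd86 did when adjusted over the list alone. Nos2, inducible nitric oxide synthase, stood at 158 ± 5.54 and 167 ± 10.9 FPKM (adjusted p = 0.424), Tnf at 467 ± 2.58 and 519 ± 24.2 FPKM (0.0751) and Il1b at 35.5 ± 0.739 and 37.5 ± 1.78 FPKM (0.335), control given before Fbxw11. The costimulatory genes Cd86 (2.51 ± 0.0504 and 3.28 ± 0.438 FPKM, adjusted p = 0.0840) and Cd80 (22.4 ± 1.56 and 22.9 ± 1.54 FPKM, 0.849, with its sign turned on the TPM scale) did not pass either. As a list they passed camera (median log2 fold change 0.17, adjusted p = 4.59e-08), with adjusted p = 0.0604 with an estimated correlation.

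Of the alternative (M2) activation markers, 1 of 12 tested members rose and 0 fell, and adjusted over the list alone 3 rose. The member that rose was Msr1, the class A scavenger receptor, from 46.9 ± 0.987 to 66.5 ± 1.93 FPKM (log2 fold change 0.49, adjusted p = 0.00102). The chemokine Ccl22 stood at 65.5 ± 0.794 and 70.7 ± 0.980 FPKM (adjusted p = 0.0682) and Il10 at 1.44 ± 0.0909 and 1.31 ± 0.170 FPKM (0.603). Arginase 1, Arg1, was listed at 0.142 ± 0.0655 FPKM in control and 0.0703 ± 0.0156 FPKM in Fbxw11 libraries, with at most 9 reads in a library. The mannose receptor gene Mrc1 was listed at 0.0388 ± 0.0101 and 0.0403 ± 0.0160 FPKM, and Chil3 had 0 reads in each library, which allows up to 3 reads per library. Differences in these 3 genes at such low levels were not detectable at this depth, but none of the 3 reached 1 FPKM in any library. The list did not pass camera (median log2 fold change 0.01, adjusted p = 0.491, and 0.623 with an estimated correlation).

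NF-kB target genes rose in 13 of 25 tested members and fell in 0, and adjusted over the list alone 17 rose. Ccl2, a monocyte-attracting chemokine, rose from 120 ± 4.73 to 186 ± 6.90 FPKM (log2 fold change 0.63, SE 0.044, adjusted p = 0.00102). The signalling adaptor Traf1 rose from 20.1 ± 0.508 to 28.0 ± 0.757 FPKM and Tnfaip3, the NF-kB inhibitor A20, from 13.3 ± 0.487 to 17.0 ± 0.504 FPKM. These targets passed camera (median log2 fold change 0.20, adjusted p = 3.60e-10), with adjusted p = 0.0605 with an estimated correlation, and 4 of its tested members, Tnf, Ccl5, Cxcl10 and Il1b, are also M1 markers. Of 16 chemokines and chemokine receptors 6 rose and 0 fell, and 8 rose adjusted over the list alone. Ccrl2, an atypical chemokine receptor, rose from 15.5 ± 0.855 to 28.2 ± 0.837 FPKM (log2 fold change 0.83) and the neutrophil chemokine Cxcl3 from 10.1 ± 0.635 to 14.4 ± 0.217 FPKM (0.47, 1.43-fold). This list shares 6 tested members with the NF-kB targets. It passed camera (median 0.15, adjusted p = 3.27e-05), with adjusted p = 0.137 with an estimated correlation.

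Interferon-stimulated genes rose in 16 of 31 tested members and fell in 1, and adjusted over the list alone 18 rose and 1 fell. Ifit2 rose from 58.3 ± 2.09 to 94.7 ± 3.79 FPKM (log2 fold change 0.69, SE 0.043, adjusted p = 0.000724) and Ifit1 from 58.1 ± 0.203 to 87.9 ± 4.09 FPKM (0.59). Both encode antiviral RNA-binding proteins. Oasl1 rose from 188 ± 2.34 to 258 ± 1.40 FPKM (0.46) and the antiviral GTPase Mx2 from 34.0 ± 1.02 to 48.8 ± 1.28 FPKM (0.51). Ifi27l2a, as given above, was the member that fell. Together they passed camera (median log2 fold change 0.17, adjusted p = 3.60e-10) and also with an estimated correlation (adjusted p = 0.0153).

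Cell cycle genes fell together. Of 29 tested S phase genes 27 fell and 0 rose, and of 31 G2 and M phase genes 28 fell and 0 rose. Adjusted over the list alone, 28 and 30 fell. Mcm6, a subunit of the replicative helicase, fell from 57.6 ± 1.46 to 36.5 ± 0.269 FPKM (log2 fold change -0.64, SE 0.032, adjusted p = 0.000377) and Mcm7 fell from 25.2 ± 0.230 to 17.1 ± 0.398 FPKM (-0.54). Rrm2, of ribonucleotide reductase, fell from 38.4 ± 0.161 to 23.1 ± 1.04 FPKM (-0.71) and Uhrf1, which maintains DNA methylation, from 22.3 ± 0.369 to 13.9 ± 0.253 FPKM (-0.65). The proliferation marker Mki67 fell from 21.6 ± 0.371 to 12.7 ± 0.668 FPKM (-0.73, SE 0.045, adjusted p = 0.000669), and the mitotic genes Bub1, Cenpe and Hmmr fell by 0.64, 0.57 and 0.57 on the log2 scale (1.61-fold, 1.55-fold and 1.597-fold in mean FPKM). Both lists passed camera (medians -0.44 and -0.45, adjusted p = 8.56e-27 and 6.84e-26) and kept the call with an estimated correlation (adjusted p = 0.0130 and 0.00677).

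Of 17 tested p53 target genes 0 fell and 1 rose, Plk2, a kinase induced by p53, from 130 ± 2.09 to 166 ± 0.756 FPKM (log2 fold change 0.36), also adjusted over the list alone. Mdm2, the ubiquitin ligase of p53, stood at 71.3 ± 1.49 and 69.2 ± 0.619 FPKM (adjusted p = 0.457). Camera called the list narrowly (median 0.10, adjusted p = 0.0436), with adjusted p = 0.205 with an estimated correlation, and lost the call under 10 of 21 alternatives.

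ATF4 and unfolded protein response genes rose in 8 of 25 tested members and fell in 1, Edem1, of endoplasmic reticulum degradation, which was named after its value was seen and lost its call under 8 alternatives. Adjusted over the list alone, 14 rose and 1 fell. The stress-induced transcription factor Atf3 rose from 538 ± 7.54 to 719.5 ± 8.84 FPKM (log2 fold change 0.42, SE 0.030, adjusted p = 0.00106), beside Hspa5 above. Xbp1 rose by a log2 fold change of 0.26 and Sel1l by 0.22. This group passed camera (median 0.16, adjusted p = 4.28e-07), with adjusted p = 0.0547 with an estimated correlation. Of 21 NRF2 target genes 2 rose and 0 fell (3 and 1 adjusted over the list alone), the cystine transporter gene Slc7a11 (0.19) and thioredoxin reductase Txnrd1 (0.13). These calls were lost under 9 and 12 alternatives, and the list did not pass (adjusted p = 0.982).

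Some genes of lipid metabolism fell. Of 22 cholesterol synthesis genes 1 fell and 0 rose, and 7 fell adjusted over the list alone. The list passed camera (median -0.10, adjusted p = 0.00146), with adjusted p = 0.249 with an estimated correlation. Of 10 liver X receptor target genes 3 fell, and 4 adjusted over the list alone. They were the desaturase Scd2, from 178 ± 0.984 to 150.1 ± 2.05 FPKM (-0.24), the lipid transfer protein Pltp, from 2.47 ± 0.105 to 1.52 ± 0.0362 FPKM (-0.46, 1.63-fold), and the cholesterol exporter Abcg1, from 21.5 ± 0.317 to 18.5 ± 0.0645 FPKM (-0.20). That list did not pass camera (adjusted p = 0.112).

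Few genes of energy metabolism passed the test. Of 20 tested gene identifiers of glycolysis 3 rose and 0 fell, and adjusted over the list alone 3 rose and 2 fell. Pfkfb3, which makes an activator of phosphofructokinase, rose from 6.41 ± 0.274 to 8.73 ± 0.319 FPKM (log2 fold change 0.39, 1.36-fold), with Hk3 at 0.21 and the glucose transporter Slc2a1 at 0.14, whose calls were lost under 11 and 13 alternatives. Gapdh, named after its value was seen, averaged 4.12 FPKM over the libraries. It has many pseudogene copies, and how reads that match several copies were counted is not given in the sources used here, so its value is uncertain. None of 35 nuclear respiratory chain genes, 13 mitochondrially encoded genes or 46 cytosolic ribosomal protein genes passed the limma test, 0 also adjusted over the list alone. At an unadjusted p under 0.05 there was 1 gene in each of these 3 lists, and voom on recovered reads called 0, 1 (mt-Nd2) and 0. The adjusted p from camera was 0.477 for glycolysis, 0.957 for the respiratory chain, 0.365 for mitochondrially encoded genes and 0.992 for ribosomal protein genes, whose median (-0.01) had the other sign from their mean and from camera's direction. Among mitochondrially encoded genes, mt-Cytb stood at 1594 ± 105 and 1523 ± 106 FPKM (limma adjusted p = 0.612). Hypoxia genes rose in 2 of 16 members, also adjusted over the list alone (Ndrg1, 0.22, and Slc2a1), and circadian clock genes in 1 of 11 with 1 fall (Bhlhe41, 0.33 or 1.33-fold, and Nr1d2, -0.29 or 1.28-fold, calls lost under 7 and 9 alternatives), 2 and 1 adjusted over the list alone. Neither list passed (adjusted p = 0.982 and 0.780).

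Phagocytic receptors and opsonins rose in 8 of 22 tested members and fell in 2, and adjusted over the list alone 10 rose and 4 fell. The complement receptor genes C3ar1 and Itgam rose from 93.7 ± 2.08 to 126 ± 1.05 FPKM (log2 fold change 0.43, adjusted p = 0.00102) and from 19.8 ± 0.746 to 27.9 ± 1.22 FPKM (0.47). The integrin Itgav fell from 26.4 ± 0.288 to 20.7 ± 0.701 FPKM (-0.33). The list passed camera (median 0.09, adjusted p = 0.0441), with adjusted p = 0.263 with an estimated correlation, and lost the call under 10 of 21 alternatives. Lysosomal genes rose in 3 of 31 members and fell in 1, Gpnmb, also adjusted over the list alone. Atp6v0d1, of the proton pump, rose by a log2 fold change of 0.31, and the protease Ctsl and the galactosidase Gla by 0.18 each, calls lost under 11 and 10 alternatives. The list passed camera at adjusted p = 0.0468 (0.372 with an estimated correlation) and lost the call under 15 of 21 alternatives.

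Osteoclast genes, which RAW264.7 cells can induce when they differentiate, fell in 3 of 12 tested members and rose in 1, with 4 falls and 1 rise adjusted over the list alone. Nfatc1, the master transcription factor of osteoclasts, fell from 11.7 ± 0.867 to 7.42 ± 0.602 FPKM (1.57-fold, log2 fold change -0.59, SE 0.072, adjusted p = 0.00565). Acp5, tartrate-resistant acid phosphatase, fell from 7.66 ± 0.553 to 4.74 ± 0.574 FPKM (-0.60, 1.61-fold), and Car2 was the other. The kinase Src rose from 1.77 ± 0.0367 to 2.70 ± 0.0912 FPKM (0.42, 1.53-fold). Camera called this list (median -0.10, adjusted p = 0.0125), with adjusted p = 0.411 with an estimated correlation, and lost the call under 3 of 21 alternatives.

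Transcripts of β-TrCP substrates went both ways, and of the SCF complex genes listed with them only Fbxw11 passed the threshold. Of 21 tested members of this list 4 rose, Fbxw11 included, and 3 fell, and adjusted over the list alone 5 rose and 3 fell. The NF-kB inhibitors Nfkbib and Nfkbia rose by log2 fold changes of 0.35 (SE 0.067, adjusted p = 0.0242) and 0.24 (SE 0.036, adjusted p = 0.0122), the former call lost under 6 alternatives. Clspn, a checkpoint adaptor of DNA replication, fell from 5.53 ± 0.533 to 3.11 ± 0.152 FPKM (-0.67, 1.78-fold). Nfkbib and Nfkbia are also members of the NF-kB target list, and the falls other than Clspn are also members of the G2 and M phase list. The list of SCF genes and substrates did not pass camera (adjusted p = 0.491). These are transcript levels, and protein levels were not analysed here. Of the Wnt/β-catenin target genes 3 were tested, too few for camera. Ccnd1, cyclin D1, fell from 17.4 ± 0.376 to 14.2 ± 0.609 FPKM, also adjusted over the list alone, and Cd44 stood at 38.6 ± 0.864 and 40.4 ± 0.569 FPKM (adjusted p = 0.267).

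Growth factor, cytokine and Toll-like receptor genes, taken as a single list, rose in 7 of 25 tested members and fell in 1. Adjusted over the list alone, 8 rose and 1 fell. Tnfrsf1b, the type 2 tumour necrosis factor receptor, rose from 87.0 ± 3.93 to 129 ± 4.67 FPKM (log2 fold change 0.56, adjusted p = 0.00148) and the lipopeptide receptors Tlr1 and Tlr6 by 0.44 and 0.31 (1.39-fold and 1.27-fold in mean FPKM). Among inflammasome and cell death genes 3 of 21 rose and 2 fell, and adjusted over the list alone 4 rose and 2 fell. The anti-apoptotic Bcl2l1 rose by a log2 fold change of 0.26 and Nlrp3 by 0.19, calls lost under 4 and 11 alternatives. MAPK immediate early and feedback genes split, with 3 of 20 rising and 3 falling, and 5 and 4 adjusted over the list alone. Dusp1, a MAPK phosphatase, rose by 0.41 and Junb by 0.30, while Spred1 fell by 0.26 and Egr1 fell by 0.29 on the log2 scale, with the calls of Junb and Egr1 lost under 6 and 5 alternatives. None of 15 antigen presentation genes passed, also adjusted over the list alone: Cd74 stood at 367 ± 13.6 and 404 ± 16.3 FPKM (limma adjusted p = 0.116) and B2m at 970.4 ± 50.4 and 836 ± 55.6 FPKM (0.0843). At an unadjusted p under 0.05 there were 4 such genes, voom called 3 (B2m, Cd74 and Tap1), and the list's mean had the other sign from its median (0.01) and from camera's direction. None of these 4 lists passed camera (adjusted p = 0.108, 0.491, 0.166 and 0.992).

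**Figure D3:**
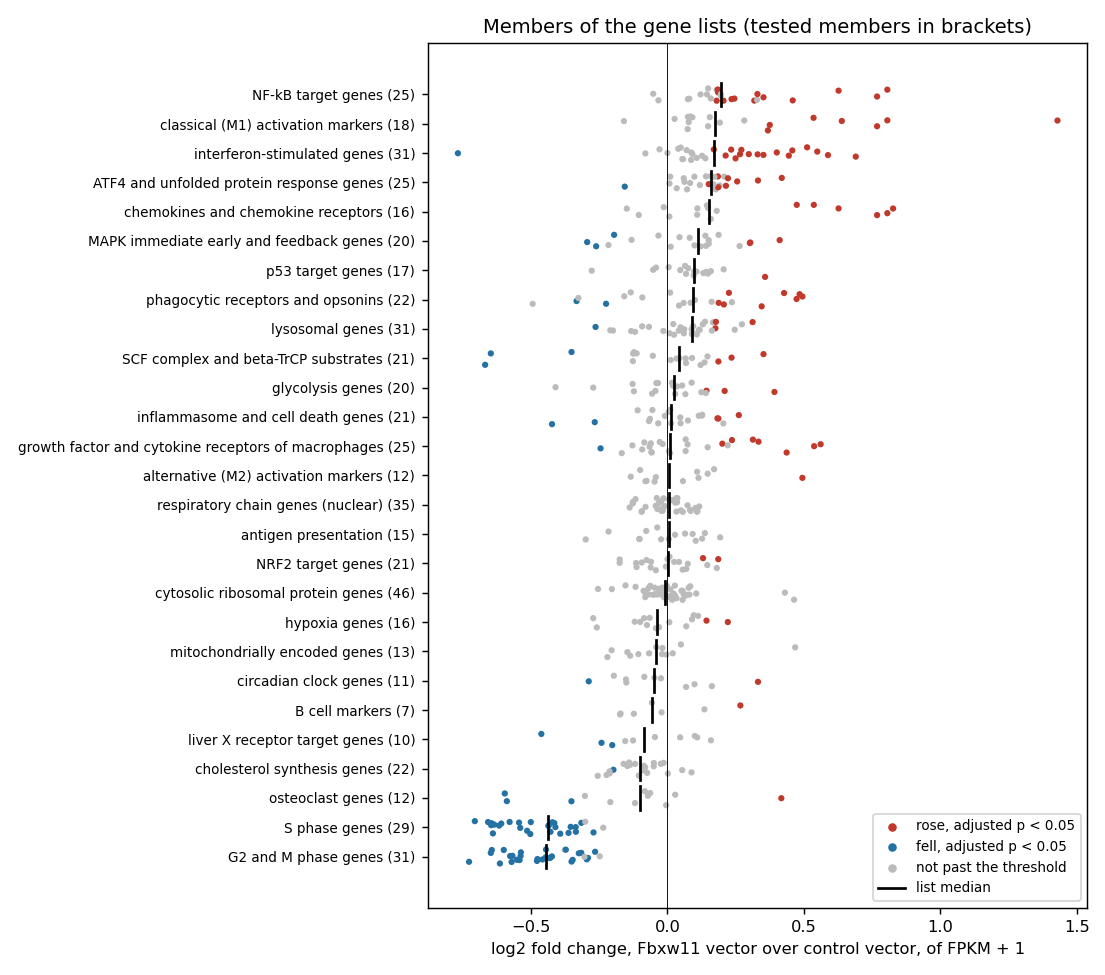
Log2 fold change of FPKM + 1 (Fbxw11 vector over control vector) of the tested members of 27 gene lists, with a point per gene, a black bar at each list's median and Fbxw11 itself not drawn. Members that rose are red and those that fell blue, and the S phase and the G2 and M phase lists lie lowest, with medians of -0.44 and -0.45.

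Few markers of other cell types reached the filter. No fibroblast or epithelial marker reached the filter, the highest, named after their values were seen, being Lum at 0.530 FPKM in control and 0.537 FPKM in Fbxw11 libraries and Epcam at 0.0264 and 0.0519 FPKM. Of 7 tested B cell markers 1 rose, Ighm, from 16.2 ± 0.761 to 19.7 ± 0.183 FPKM, also adjusted over the list alone, and the list did not pass camera (adjusted p = 0.982). Of the T and NK cell markers 2 were tested, and 1 rose, Cd5, from 0.870 ± 0.0302 to 1.47 ± 0.154 FPKM, while Lck stood at 5.44 ± 0.577 and 5.04 ± 0.255 FPKM (adjusted p = 0.505). Of the dendritic cell markers 2 were tested, and 1 rose, the integrin Itgax, from 0.958 ± 0.138 to 1.74 ± 0.157 FPKM, while Ccr7 stood at 4.21 ± 0.197 and 4.63 ± 0.300 FPKM (0.300). The rises of Cd5 and Itgax were also counted adjusted over the list alone, and each was lost under 8 alternatives. The granulocyte marker S100a8 stood at 3.34 ± 0.759 and 4.49 ± 1.18 FPKM (0.324). Ribosomal RNA took 0.0266% ± 0.000426 of reads in control and 0.0381% ± 0.00292 in Fbxw11 libraries, and mitochondrial protein-coding genes 1.64% ± 0.0899 and 1.55% ± 0.126.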

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

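The search was chosen after the data were seen. It covered genes under the 1 FPKM filter, which the comparison did not test, and asked for at least 30 reads over the 6 libraries, groups that do not overlap and a difference of at least 3-fold. Of 2146 genes screened, 5 were higher in the Fbxw11 libraries and 8 were lower. Each ratio below is one of reads scaled to depth, with an exact 95% interval that covers counting error only and not the spread between libraries. The genes were chosen on these same reads, so the ratios and intervals lean away from 1 and are no test. How many genes would be found by chance was not computed.

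Upk3b, a uroplakin gene, had 31 reads over the 3 Fbxw11 libraries against 5 in the controls, a ratio of 6.38 (2.46 to 21.0). Tnn, tenascin N, had 181 against 57 reads, a ratio of 3.27 (2.41 to 4.48). Il12b, the shared subunit of interleukins 12 and 23 and a member of the M1 list, had 25 against 8 reads, a ratio of 3.21 (1.41 to 8.24). The olfactory receptor gene Olfr129 had 59 against 19 reads, a ratio of 3.19 (1.88 to 5.67). The secretogranin gene Scg2 had 157 against 52 reads, a ratio of 3.10 (2.26 to 4.33). The 8 lower genes were N4bp3 (31 reads in the controls against 7, a ratio of control to Fbxw11 of 4.31, 1.86 to 11.6), Cpe (49 against 14, 3.40, 1.85 to 6.68), Myl4 (27 against 8, 3.28, 1.45 to 8.36) and Scin (67 against 20, 3.26, 1.95 to 5.67). The others were Rtl6 (30 against 9, 3.24, 1.5004 to 7.76), Zfp651 (26 against 8, 3.16, 1.39 to 8.08), Atp2b3 (47 against 15, 3.05, 1.67 to 5.87) and Bmp1 (25 against 8, 3.04, 1.33 to 7.79). No explanation was tested for these genes.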

How the results depend on the processing

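The voom test, the plain read sums and the joint removal of both libraries numbered 3 were chosen after the result was seen. Of the 1007 changed genes, 968 were also among the 1500 called by voom on recovered reads. The count was 596 (289 rose, 307 fell) with no filter, where more genes shared the adjustment and the mean-variance trend was fitted anew. These 2 changes were not separated. A block on the replicate number gave 621 (303 and 318). Whether same-numbered libraries belong together is not given in the sources used here, and their correlations do not settle it. They were taken on what remained after each gene's group mean was subtracted, so they are not correlations of whole libraries. Same-numbered libraries then correlated at 0.0361, 0.0405 and 0.189, the last being the highest of all pairs across the groups. Differently numbered ones ranged from -0.162 to 0.148, and control library 1 correlated best with Fbxw11 library 2 (0.148). An absolute log2 fold change of at least 1 left 16 (14 and 2) and an adjusted p below 0.01 left 343 (162 and 181). With a single library left out the count ranged from 410 to 801, the rises from 190 to 418 and the falls from 220 to 383. With both libraries numbered 3 left out, 698 genes changed (363 rose, 335 fell) and 7 lists passed in place of 12. Lists past the threshold fell to 3 with an estimated correlation, numbered 16 by fry, and ranged from 8 to 12 with a library left out.

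The log2 fold change of Fbxw11 stayed between 2.87 and 2.88 with a library left out. Of 105 other genes named here and past the threshold, 69 kept the call under every alternative run other than the minimum log2 fold change and the lower adjusted p, 105 kept it under voom and 86 under the block. Of the 36 that lost it at least once, 22 lost it at least 5 times: Lyz2, Slc2a1, Txnrd1, Ctsl, Hk3, Nlrp3, Gla, Nr1d2, Slc7a11, Cd5, Edem1, H1f2, Itgax, Bhlhe41, Csf2rb, Cst3, E2f2, Junb, Nfkbib, Csf3r, Egr1 and Mnd1. The others, with 1 to 4 losses, were Bcl2l1, Abcg1, Csf2ra, Csf3, Sqstm1, E2f1, Ighm, Ndrg1, Nfkbia, Ccnd1, Csf1, Hspa5, Ptgs2 and Src. The only reversals were of Cd80, which was not past the threshold: -0.0154 on the TPM scale, -0.00919 over plain read sums, -0.0129 without both libraries numbered 3, and -0.0151 and -0.00275 without control library 2 or Fbxw11 library 3, in a range of -0.0151 to 0.0813 with a library left out. Of the genes not past it, B2m, Cd74, Cd86 and Tnf passed under at least 1 alternative, B2m under voom with an adjusted p of 0.00991. Causes not named here were not tested. Depth limits what can be said of Arg1, Mrc1 and Chil3.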

Other observations

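Tests of the share of cycling cells, of Ifna paralogs, of genomic DNA and of other splits of the libraries were chosen after the result was seen, as were the gene families and single genes named here.

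Families taken from gene symbols (151 stems with at least 8 tested members) went both ways. Of 24 kinesin genes (Kif) 8 fell and 0 rose (median log2 fold change -0.22, camera adjusted p = 1.46e-06, and 0.249 with an estimated correlation), 4 of them (Kif11, Kif20a, Kif20b and Kif23) being members of the G2 and M phase list. Of 17 Rad genes 7 fell, and of 19 nucleoporin genes (Nup) 7 fell (median -0.16). Of 8 tested members of the E2F and DP transcription factor family 4 fell, Tfdp1, E2f1, E2f8 and E2f2, the last call lost under 6 alternatives, and E2f1 and E2f8 are members of the S phase list. Upward, camera called the stems Bcl (3 of 13 rose, adjusted p = 0.000894), Dusp (1 of 17, 0.0437) and Ccl (3 of 9, 0.0488), with adjusted p = 0.826, 0.870 and 0.870 with an estimated correlation. A second screen covered 21 transcription factor families with at least 5 tested members, E2F among them. In it camera called bZIP upward, of which 5 of 37 rose and 1 fell (adjusted p = 0.00154, and 0.139 with an estimated correlation). Also upward were STAT, SAND and IRF (camera adjusted p = 0.00428, 0.0220 and 0.0260). Called downward were E2F, HMG and MYB (camera adjusted p = 0.00428, 0.00428 and 0.0307). No family passed with an estimated correlation. Of 10 tested histone genes of the replication-dependent clusters and linker histones, by contrast, 0 fell and 1 rose, H1f2, a call lost under 8 alternatives (median 0.09).

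Several single genes not given above changed. Of 8 tested genes with the stem Csf 5 rose and 2 fell, and camera did not call them (adjusted p = 0.480, and 0.975 with an estimated correlation). Csf3, which encodes G-CSF, rose from 526 ± 13.2 to 648 ± 33.5 FPKM and Csf1 from 5.17 ± 0.258 to 7.17 ± 0.493 FPKM (1.39-fold). The receptor subunits Csf3r and Csf2ra rose (log2 fold changes 0.54 and 0.33, or 1.69-fold and 1.27-fold in mean FPKM), while Csf2rb and Csf2rb2 fell (-0.24 and -0.37, or 1.21-fold and 1.32-fold), and the calls of Csf3r, Csf2rb, Csf3, Csf2ra and Csf1 were lost under 5, 7, 3, 3 and 1 alternatives. Lipocalin 2, Lcn2, rose from 56.6 ± 3.63 to 125 ± 3.57 FPKM, the protease inhibitor Slpi from 11.9 ± 1.11 to 26.6 ± 2.68 FPKM and Adgre1, the F4/80 antigen, from 55.0 ± 1.33 to 80.4 ± 2.34 FPKM. Genes known to respond to interferon did not all move with Ifit1 and Ifit2: Ddx60 fell from 13.7 ± 0.335 to 8.40 ± 0.406 FPKM, beside Ly6e, Tlr3, Apol9a and Ifi27l2a. These were grouped here because they fell. In the fixed list of interferon-stimulated genes, 16 of 31 tested members rose and 1, Ifi27l2a, fell.

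The fall of S, G2 and M phase genes was set against genes matched on length, GC content and expression, which reached its median of -0.44 in 0% of 1000 draws, the lowest draw being -0.0783. A smaller share of cycling cells in the Fbxw11 libraries may account for it. The S phase median differed from the G2 and M median by 0.00964 (95% bootstrap interval over genes -0.126 to 0.108). The interval is too wide to tell, and it leaves out the spread between libraries. Equal medians could not decide it either, since lower expression of these genes in each cell could also lower both lists alike. The histone genes above did not fall, but whether the libraries hold transcripts without a poly(A) tail is not given in the sources used here. An effect of the Fbxw11 vector and a difference between cultures or transductions that goes with it cannot be told apart here, and neither was tested.

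The rise of type I interferon genes is not explained by reads shared between Ifna copies alone, since Ifnb1, which has no near-identical copy, rose by a log2 fold change of 1.61. Genomic DNA would raise other intronless genes, and the mean over 1195 olfactory receptor genes differed by -0.00193 FPKM. No single Fbxw11 library carried it, as the median of Ifnb1, Ifna1, Ifna2, Ifna4 and Ifna5 stayed between 1.54 and 1.62 without each in turn. An innate response to Fbxw11 protein, to unequal vector dose or to culture conditions could raise these genes, and none of these possibilities was tested.

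Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave 1007 changed genes, and the highest of the others gave 2. For gene lists past camera 1 split, the real one, reached 12, and the others between 3 and 9, while with an estimated correlation 3 lists passed in the real split and 0 in the others. The S phase and the G2 and M phase lists passed camera at the preset correlation in 9 of 9 other splits, M1 markers and NF-kB targets in 5, interferon-stimulated, ATF4 and cholesterol synthesis genes in 4, chemokines in 2, osteoclast genes in 1, and phagocytic, p53 and lysosomal lists in 0. Each other split still sets 2 libraries of a group and 1 of the other against the reverse, and so holds part of the real difference. With 10 splits a share under 0.05 cannot be had.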
